A study of Gadus morhua with 30 samples.

How the data were processed

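RNA sequencing was used to measure gene expression in liver explants of Atlantic cod (Gadus morhua), slices of liver kept in culture, after exposure to organophosphate flame retardants or to the vehicle dimethyl sulfoxide (DMSO). Per the labels' protocols, the explants received DMSO at 0.01% or a flame retardant, total RNA was isolated with a BioRad kit, libraries were made with an Illumina TruSeq total RNA kit, and sequencing was done on a HiSeq2000. TCPP is tris(1-chloro-2-propyl) phosphate, a chlorinated alkyl ester, and EHDPP is 2-ethylhexyl diphenyl phosphate, which carries aryl groups and no chlorine. The labels give the concentrations as high or low, with no unit, and do not give the make-up of the mixture. The files hold 30 libraries in 10 groups of 3, and the group of each library was taken from its labels for compound, concentration and hours of exposure.

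The deposited files hold raw counts of reads per gene, in whole numbers, for 22154 genes with Ensembl identifiers, followed by 5 summary lines. Per the submitters' processing notes, FastQC, TopHat, HTSeq and edgeR were used by the authors, with no versions. The genome build, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, counts of overlapping or antisense genes are uncertain, and so are counts of near-identical gene copies. The summary lines were kept out of library sizes and tests. Reads assigned to no counted feature, called reads outside genes below, made up 34.0% to 46.8% of all reads listed for a library. They may include reads within genes, since the strand setting is not given. Reads placed at more than 1 position made up 7.57% to 16.8%, and ambiguous reads 1.70% to 2.63%. Gene counts summed to between 10847723 and 18271278 per library, with a median of 15388367.

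The reference table supplied with the series, built on gadMor3.0 with 33114 rows, matched 0 of the 22154 identifiers, and the deposited files do not pair identifiers with gene names. Gene names are therefore not printed. The 32 gene lists with 732 entries that were fixed before the data were examined (among them sterol synthesis, aryl hydrocarbon receptor targets, egg proteins, hepatocyte proteins and markers of other liver cell types) could not be tested, because they are lists of symbols. The rule for named genes asked for a symbol, an adjusted p under 0.05, a mean of at least 1 log2 CPM and non-overlapping libraries, in order of fold change. It was applied without the symbol to the comparison of 24 h with 0 h, and the 2 identifiers with the largest rise and the 2 with the largest fall are printed. That change to the rule was made after the values were seen. Positions, gene lengths and GC content were not used here.

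Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 15312 genes tested and 6842 not tested. Library sizes were scaled with TMM factors. All 30 libraries entered 1 quasi-likelihood fit with a mean per group, so that groups of 3 share an estimate of the spread. The estimated coefficient of biological variation was 39.2%. Each of 22 comparisons was a contrast of group means, tested on both sides, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05. Fold changes are given on the log2 scale with their standard error (SE), derived from the quasi-likelihood F statistic. Levels are given in CPM, counts scaled to a common library total, and log2 CPM values for plots and correlations used a prior count of 2. An effect over both times is the mean of the 24 h and 48 h effects.

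The series' design text describes the replicates as biological samples, without naming fish, cultures or runs, so p-values measure the spread between these libraries. Replicate numbers were given in order of deposit and pair nothing. Counts of the 30 pairs of libraries within groups differed far beyond sampling noise, with a chi-square per degree of freedom of 34.6 to 278.5, so no library was counted as deposited more than once. Intervals and floors based on counts cover counting error only, at a level of 95%.

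Alternatives planned before the data were examined were size factors by the method of DESeq2 (RLE), DESeq2 1.42.0 itself, no filter on low counts, a fit of the compared groups only, up to 3 surrogate variables from sva 3.50.0, and each library left out in turn. For the number of surrogate variables, the method named be gave 4 and the method named leek gave 0, and 3 were used. A covariate for clusters of libraries, and a fit without the 2 libraries of highest share of reads outside genes, were added after the data were seen. The fits were tested on simulated counts for the 15312 genes, drawn from the fitted means, library sizes and dispersions, with 200 genes changed by 2, 4 or 8 times. In 1 kind of simulation the libraries were independent within groups, and in the other they carried the cluster differences seen in the data. Each kind was drawn as 1 set per comparison, so these simulated counts and shares come without a spread. The clusters were also set beside 1000 draws of independent, normally distributed libraries with the covariance between genes seen within groups. Correlations of effects that share DMSO libraries were set beside the mean of 5 simulated sets of unchanged groups. Figures were drawn with matplotlib 3.10.9.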

Results

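Gene expression was measured by RNA sequencing in cultured liver explants of Atlantic cod exposed to the flame retardants TCPP and EHDPP, to a mixture, or to the vehicle DMSO. The series asks how organophosphate flame retardants affect cod liver. Vehicle explants were sampled at 0, 24 and 48 h, high concentrations of TCPP, EHDPP and the mixture at 24 and 48 h, and a low concentration of TCPP at 24 h. Each of the 10 groups held 3 libraries. The libraries held 10847723 to 18271278 counts on genes, and 16431 to 17999 of the 22154 genes had at least 1 count in a library. The deepest group on average was the mixture at 48 h, with 17410000 ± 917600 counts (SD, n = 3), and the shallowest was TCPP at 48 h, with 12480000 ± 1560000 (SD, n = 3). The 10 genes with the most counts took 10.1% to 22.5% of a library.

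The largest principal component divided the libraries at 0 h from those kept longer in culture. Hours in culture and hours of exposure to vehicle or compound coincide, so they are not told apart. The first principal component of log2 CPM held 27.8% of the variance and placed the 3 libraries at 0 h between 105 and 121. The 27 cultured libraries lay between −56.5 and 42.3, with DMSO and compound libraries intermixed.

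**Figure D1:**
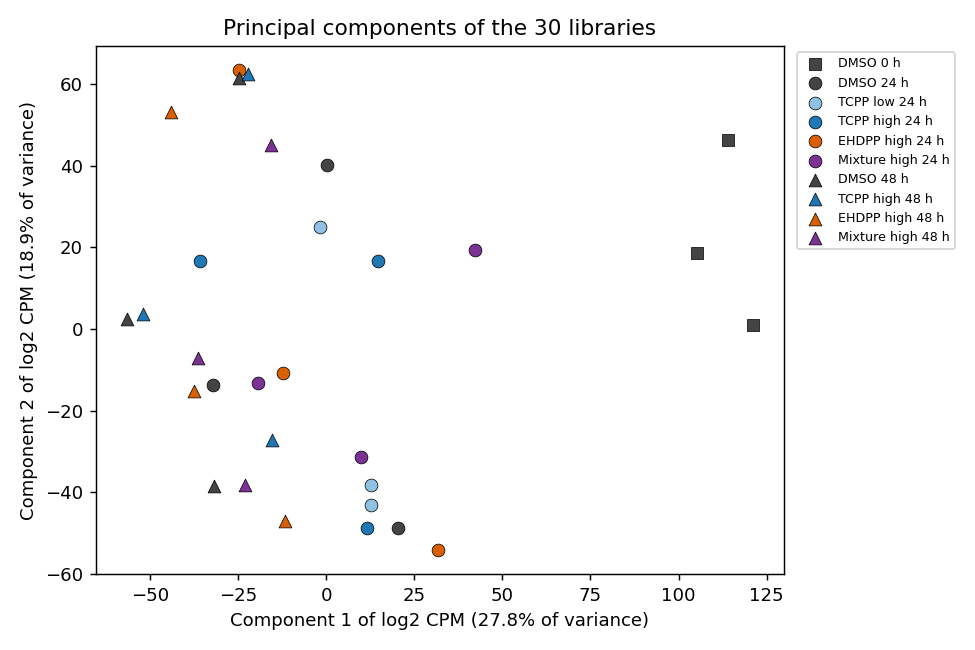
Each point is 1 of the 30 libraries, placed by the first and second principal components of log2 CPM of 15312 genes (arbitrary units), with colour for the treatment and shape for the hours. The 3 libraries at 0 h lie at 105 or more on the first component, and all 27 cultured libraries lie at 42.3 or less.

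The libraries of a group also differed from each other along lines that ran through all groups. After the group means were removed, the 30 libraries were grouped by correlation into 3 clusters. The number 3 was set, not estimated from the data. Each of the 10 groups had 1 library in each cluster. The clusters also lay apart in part on the second principal component of log2 CPM. There 1 cluster ran from 16.56 to 63.42, and another from −54.15 to −27.19 except for its 0 h library at 0.86. The last cluster overlapped both, from −38.18 to 18.59. Every library, 30 of 30, correlated best with a library of its own cluster. The median correlation across genes was 0.47 between libraries of different groups in 1 cluster and −0.22 between clusters. Single values overlapped, with a lowest of 0.0023 within clusters and a highest of 0.4 between them. The clusters were formed from these correlations, and removing the group means lowers the values between clusters. The medians and the 30 of 30 therefore describe the clusters and do not by themselves test them. Genes are not independent replicates, so these correlations describe the libraries. The first 2 components of the spread within groups held 56.1% of it. The labels name no fish, batch or run for these clusters.

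**Figure D2:**
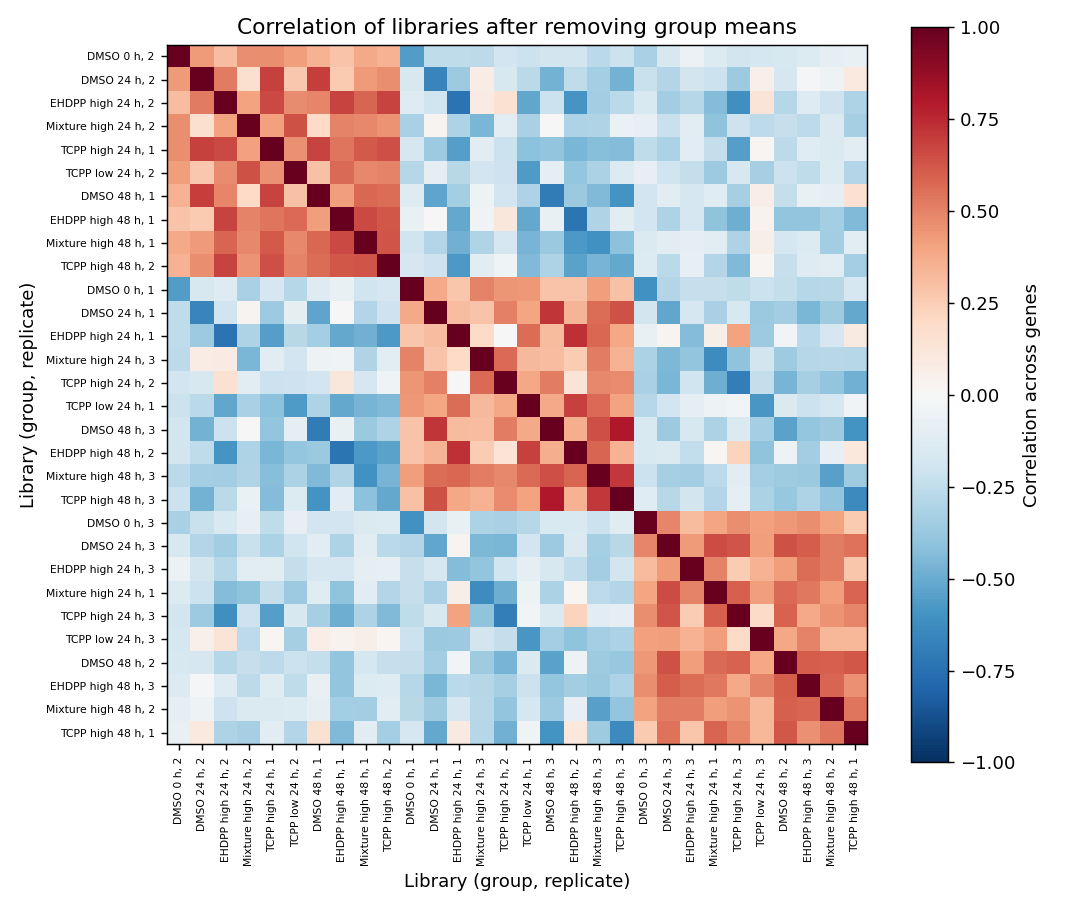
The map gives the correlation across 15312 genes of each pair of the 30 libraries after the mean of each group was removed from log2 CPM, with libraries ordered by cluster on both axes and colour for the correlation. The 3 blocks along the diagonal hold 1 library of each of the 10 groups. The median correlation was 0.47 inside blocks between groups and −0.22 outside, and the blocks were formed from these correlations.

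The vehicle comparisons asked how liver explants changed in culture with DMSO. After 24 h in DMSO, 4588 of the 15312 genes tested differed from 0 h, 2630 higher and 1958 lower. After 48 h, 6026 genes differed from 0 h, 3249 higher and 2777 lower. Which direction had more genes at 48 h turned with the fit, at 4127 higher and 4342 lower with surrogate variables, 3781 and 3817 with the cluster covariate, and 2535 and 2537 in the compared groups only. The changes were large for many genes, with 1628 of the called genes at least 2-fold higher and 1498 at least 2-fold lower at 24 h, by the fitted values. At 48 h these numbers were 2052 and 2318, and 417 genes were at least 8-fold lower against 217 at least 8-fold higher. The planned fit with 3 surrogate variables called 7304 genes at 24 h, 3596 higher and 3708 lower, including all 4588. Among the genes called higher at 48 h, 65 had at most 3 counts over the 3 libraries at 0 h. Among those called lower, 18 had at most 3 counts over the 3 libraries at 48 h.

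The genes called at 24 h were for the most part called again at 48 h. Of the genes higher at 24 h, 2315 were also higher at 48 h, where independent lists of these sizes would share 558. Of those lower at 24 h, 1637 were also lower at 48 h, against 355 for independent lists. No gene, 0 of 15312, was called in opposite directions, against 477 and 416 for independent lists. The median size of change of the 3952 genes called at both times was 1.35 at 24 h and 1.48 at 48 h on the log2 scale, and 2709 of them (68.5%) had the larger value at 48 h. Another 2074 genes were called at 48 h only, of which 2037 had the same sign at 24 h. The comparisons share the libraries at 0 h. The correlation of both effects across genes was 0.91, where simulated unchanged groups gave 0.49, and the covariance was 1.26 against a simulated 0.133. The libraries at 0 h are too few to be split between the comparisons, so part of the overlap may come from them.

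The 2315 genes higher at both times took 6.73 ± 0.12% of normalised counts at 0 h (SD, n = 3), 17.2 ± 2.10% at 24 h and 21.4 ± 2.18% at 48 h in DMSO. The 1637 genes lower at both times went from 7.02 ± 0.75% to 2.41 ± 0.46% and 2.23 ± 0.10%. Because these genes were selected on the DMSO libraries, their DMSO shares are not independent of the selection. The compound groups did not enter these contrasts, though their libraries shared the filter, the scaling and the estimate of the spread. In these groups the first set took 15.6% to 17.4% on average at 24 h and 20.4% to 20.6% at 48 h. The second set took 2.48% to 2.81% at 24 h and 2.33% to 2.47% at 48 h. These compound means lay within 1 SD of the DMSO mean of their time, except for the lower set at 48 h in EHDPP (2.38%) and the mixture (2.47%), which lay above it.

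**Figure D3:**
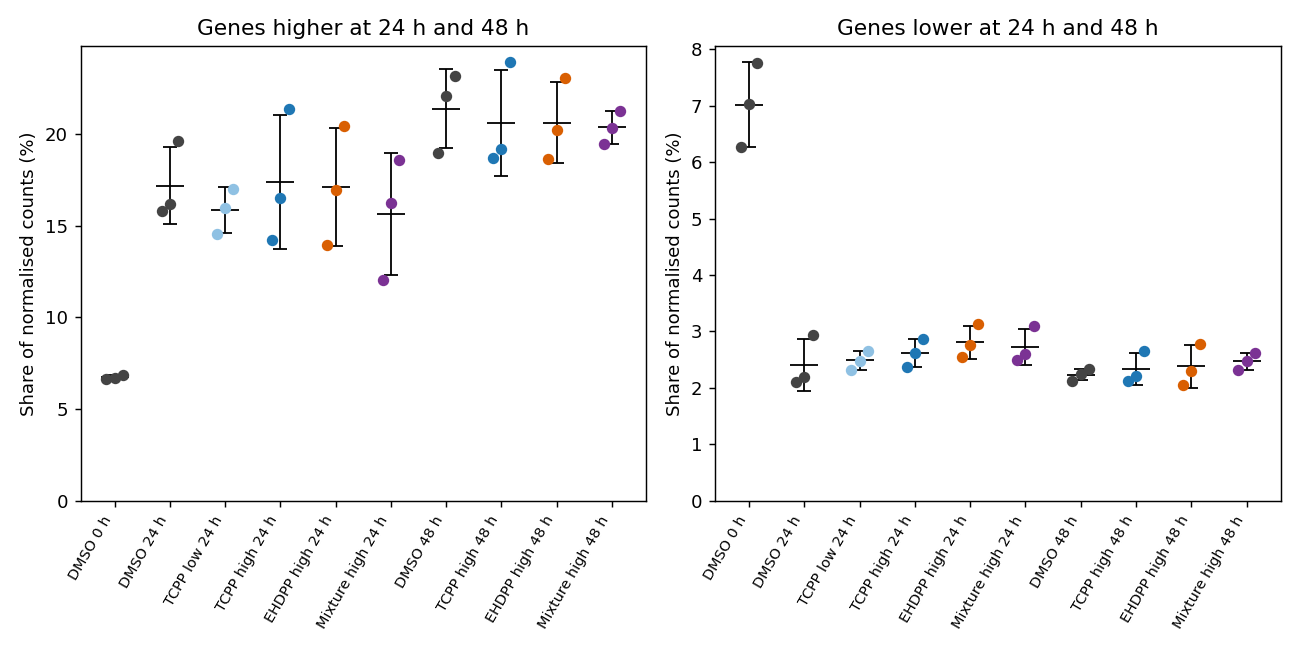
Points are single libraries, bars are the mean and SD of 3 libraries, and the vertical axes give the percent of normalised counts taken by 2315 genes called higher and 1637 genes called lower in DMSO at both 24 h and 48 h against 0 h. All 27 cultured libraries lie above the libraries at 0 h in the left panel and below them in the right panel.

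Of the identifiers with the largest rise at 24 h, ENSGMOG00000005503 had 0 counts in the 3 libraries at 0 h. It reached 7.15 ± 5.72 CPM at 24 h and 13.8 ± 6.69 CPM at 48 h (SD, n = 3), at least 109-fold and at least 201-fold above a floor of 3 counts over the group at 0 h. Its adjusted p was 0.00096 at 24 h and 0.00024 at 48 h by edgeR. ENSGMOG00000016719 had 2 counts at 0 h and 30.4 ± 38.9 CPM at 24 h, a ratio of 545 with a counting interval of 151 to 4510 (edgeR adjusted p = 9.2e-05). Its level at 48 h was 19.6 ± 14.6 CPM. Without replicate 1 of DMSO at 24 h, its fitted log2 fold change at 24 h went from 9.09 to 7.20. Leaving out replicate 2 of DMSO at 24 h moved that of ENSGMOG00000005503 from 9.79 to 9.18, and that of ENSGMOG00000011063 to −6.21. ENSGMOG00000011063 fell from 346 ± 91.3 CPM at 0 h to 11.9 ± 12.6 CPM at 24 h, a log2 fold change of −4.86 ± 0.85 (SE, edgeR adjusted p = 0.00015), and to 5.69 ± 3.10 CPM at 48 h. ENSGMOG00000017338 fell from 191 ± 39.8 CPM to 7.67 ± 5.03 CPM at 24 h, by −4.64 ± 0.84 on the log2 scale (SE, edgeR adjusted p = 0.00023). At 48 h it lay at 1.30 ± 0.38 CPM, a log2 fold change of −7.21 ± 0.97 (SE, edgeR adjusted p = 4.9e-06). What these genes encode was not analysed here.

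Between 24 h and 48 h in DMSO, edgeR called 0 genes, with 1480 genes at an unadjusted p under 0.05 where uniform p-values would give 766, and 802 without replicate 2 of DMSO at 24 h. In fits of the compared libraries only, the real labels gave 921 such genes. As many came from 4 of the 10 ways to split these libraries 3 against 3, the real one included. The highest other split gave 2328, so the excess over uniform p-values is not told apart from chance. DESeq2 called 34 genes, 21 higher and 13 lower at 48 h. The fit with 3 surrogate variables called 433, 79 higher and 354 lower, and the fit with a covariate for the clusters called 6, 1 higher and 5 lower. Which direction had more genes thus turned with the fit. The 95% interval of the change excluded a 2-fold difference for 45.1% of genes and a 4-fold difference for 80.8%.

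The comparison of TCPP with DMSO asked which genes respond to the chlorinated compound. No gene was called by edgeR at the low concentration at 24 h, at the high concentration at 24 h or 48 h, or over both times, and DESeq2 also called 0 in each. Unadjusted p-values under 0.05 came from 164, 123, 191 and 186 genes, fewer than the 766 that uniform p-values would give. With 1 library left out these counts were 89 to 573, 123 to 317, 116 to 793 and 146 to 406. The highest came without replicate 1 of DMSO at 24 h for the low concentration, replicate 2 of DMSO at 24 h for the high concentration at 24 h, and replicate 3 of DMSO at 48 h for the last pair. Simulated libraries that carried the clusters gave 362 among the genes left unchanged, for the high concentration at 24 h. With the covariate for the clusters the real counts were 396, 250, 399 and 363, and with surrogate variables 458, 416, 617 and 552. For the high concentration at 24 h the simulated counts were then 788 and 763. At the high concentration, the 95% interval excluded a 2-fold difference for 53.1% of genes at 24 h, 52.0% at 48 h and 71.4% over both times. A 4-fold difference was excluded for 86.3%, 86.0% and 94.6%. In 1 simulated set with the clusters, the test found 8.96% of 67 genes with a 2-fold change in this comparison at 24 h. It found 62.7% at 4-fold and 80.3% at 8-fold. On the same simulated counts, the cluster covariate raised the share at 2-fold to 28.4% and surrogate variables raised it to 23.9%. Such shares are rough: for DMSO at 24 h against 0 h, the test without these additions found 28.4% of 67 genes at 2-fold.

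The comparison of EHDPP with DMSO gave 0 genes called by edgeR at 24 h, at 48 h and over both times. Genes at an unadjusted p under 0.05 numbered 210, 215 and 204. When 1 library was left out they were 234 to 519, highest without replicate 2 of EHDPP at 24 h, 223 to 486, highest without replicate 1 of DMSO at 48 h, and 183 to 402, highest without replicate 1 of EHDPP at 24 h. With the covariate for the clusters there were 456, 461 and 408 such genes, and with surrogate variables 614, 730 and 633. DESeq2 called 0 genes at 24 h, 1 lower gene at 48 h and 0 over both times. The 95% interval excluded a 2-fold difference for 52.0% of genes at 24 h, 50.7% at 48 h and 70.8% over both times, and a 4-fold difference for 85.2%, 85.6% and 94.5%.

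The comparison of the mixture with DMSO gave 0 genes called by edgeR at 24 h, at 48 h and over both times. Genes at an unadjusted p under 0.05 numbered 198 at 24 h, 620 at 48 h and 784 over both times. These became 189 to 541 at 24 h and 448 to 928 at 48 h with 1 library left out, highest without replicates 2 and 1 of DMSO at those times, and 543 to 1235 over both times, highest without replicate 2 of DMSO at 24 h. In 1 simulated set of libraries that carried the clusters, with no change outside 200 genes, 336 of the other genes had such p-values over both times. With the covariate for the clusters the counts were 408, 1073 and 1302, the last against 747 simulated, and with surrogate variables 705, 1779 and 2067, the last against 737 simulated. In fits of the 12 compared libraries with the covariate, treatment and DMSO labels were exchanged within clusters. The real labels gave 1 called gene over both times and 1351 genes at an unadjusted p under 0.05. As many came from 4 and 8 of the 32 exchanges, so this excess is not told apart from chance. DESeq2 called 0 genes at 24 h, 3 lower genes at 48 h and 1 lower gene over both times. With surrogate variables, 2, 2 and 4 genes were called. Of these, 2 were higher and 0 lower at 24 h, 1 and 1 at 48 h, and 2 and 2 over both times. Without the 2 libraries of highest share of reads outside genes, 1 lower gene was called at 48 h. The 95% interval excluded a 2-fold difference for 51.9% of genes at 24 h, 48.1% at 48 h and 68.0% over both times. Of genes simulated with a 2-fold change over both times, in libraries that carried the clusters, 47.8% were called, against 76.1% at 4-fold and 90.9% at 8-fold.

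**Figure D4:**
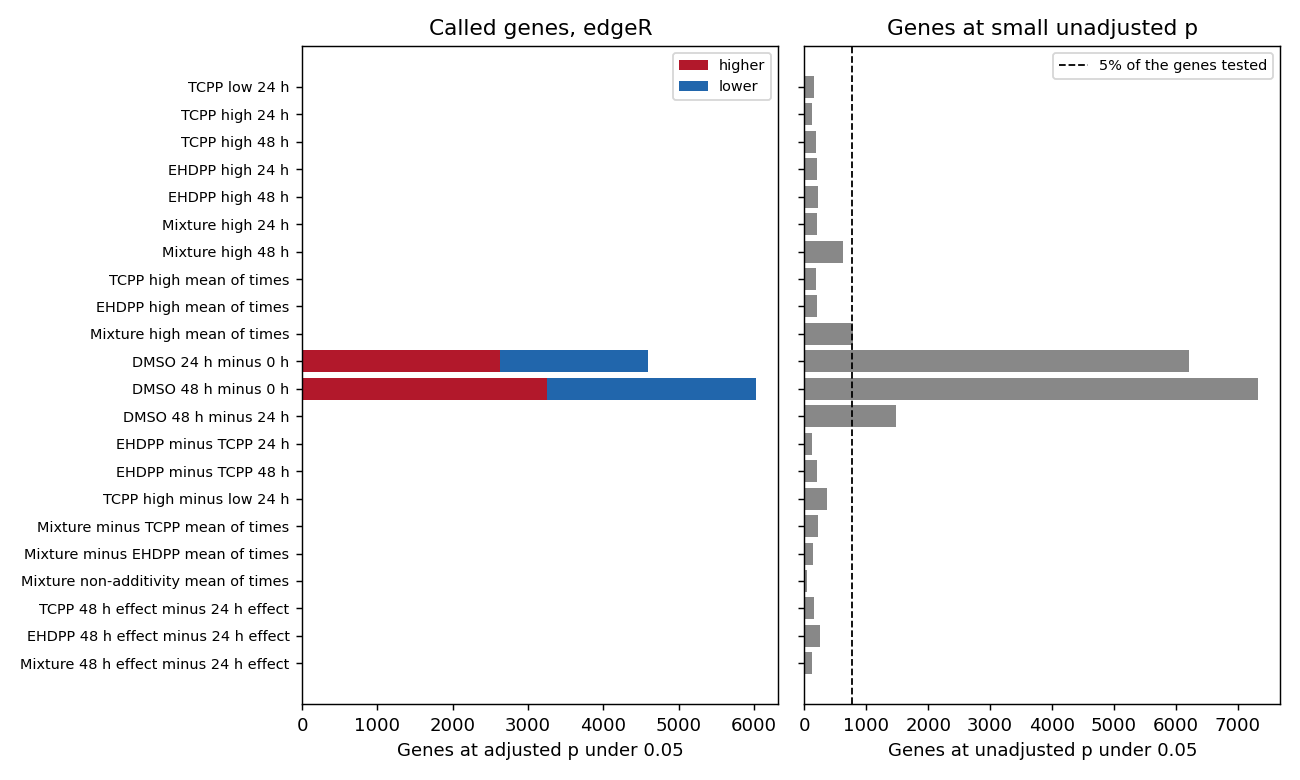
Bars give, for each of 22 comparisons, the number of genes called by edgeR at an adjusted p under 0.05 (left, higher and lower stacked) and the number at an unadjusted p under 0.05 (right), with a dashed line at the 766 that uniform p-values would give. Calls came from DMSO at 24 h and 48 h against 0 h alone, 4588 and 6026 genes, and the other 20 comparisons called 0.

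TCPP and EHDPP, which differ in their chlorinated alkyl against aryl and alkyl ester groups, were compared directly at matched times and the high label of each. The labels do not say whether both high concentrations were equal. Both edgeR and DESeq2 called 0 genes between them at 24 h and at 48 h, with 124 and 210 genes at an unadjusted p under 0.05 by edgeR. Leaving out 1 library gave 125 to 490, highest without replicate 2 of EHDPP at 24 h, and 124 to 565, highest without replicate 1 of TCPP at 48 h. The 95% interval of EHDPP minus TCPP lay within 2-fold for 53.1% of genes at 24 h and 49.6% at 48 h, and within 4-fold for 86.6% and 85.8%. The remaining genes could differ by more than these sizes without being called. High minus low TCPP at 24 h also gave 0 calls by both tools, with 361 genes at an unadjusted p under 0.05 (157 and 674 without replicates 3 and 1 of the low concentration) and 49.0% of intervals within 2-fold; the fit with a covariate for the clusters called 1 gene, lower at the high concentration.

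The mixture was set against each compound over both times, and against the sum of both effects. Mixture minus TCPP and mixture minus EHDPP each gave 0 calls by edgeR and DESeq2, with 218 and 142 genes at an unadjusted p under 0.05. These counts were 114 to 383 with 1 library left out, the extremes without replicates 3 and 2 of TCPP at 24 h, and 107 to 349, highest without replicate 2 of EHDPP at 24 h. Their 95% intervals lay within 2-fold for 71.2% and 71.4% of genes. The departure of the mixture from the sum of the TCPP and EHDPP effects gave 0 calls by both tools. It gave 48 genes at an unadjusted p under 0.05 and 55.3% of intervals within 2-fold. With 1 library left out there were 45 to 117 such genes, highest without replicate 3 of DMSO at 48 h. This departure measures additivity only if the mixture holds both compounds, each at its high concentration, which the labels do not say. The 48 h effect minus the 24 h effect gave 0 calls by both tools for TCPP, EHDPP and the mixture, with 157, 255 and 117 genes at an unadjusted p under 0.05. Fits that left out 1 library gave 67 to 494, 205 to 563 and 82 to 327. The highest came without replicate 3 of DMSO at 48 h, replicate 2 of EHDPP at 24 h and replicate 1 of the mixture at 24 h, and the 67 without replicate 1 of DMSO at 24 h. For these differences 29.2%, 29.7% and 29.8% of intervals lay within 2-fold.

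Effects of different compounds at 1 time share their 3 DMSO libraries and therefore correlate without any effect. At 24 h, the correlation across genes was 0.55 for TCPP with EHDPP, 0.56 for TCPP with the mixture and 0.51 for EHDPP with the mixture. Simulated unchanged groups with the clusters gave 0.52, 0.51 and 0.51. The covariances, 0.0576, 0.0567 and 0.0569, lay below the simulated 0.0768, 0.0761 and 0.0764. At 48 h, the correlation was 0.39 for TCPP with EHDPP, 0.54 for TCPP with the mixture and 0.71 for EHDPP with the mixture, beside simulated values of 0.49, 0.50 and 0.51. The covariance for EHDPP with the mixture was 0.101 against a simulated 0.0753, an excess of 0.0255. For TCPP with the mixture it was 0.0758 against 0.0742, and for TCPP with EHDPP 0.0480 against 0.0745. The low and high concentrations of TCPP at 24 h correlated at 0.25, below the simulated 0.50. No called genes were shared in any of these pairs, since each list held 0. Genes are not independent replicates, and 3 control libraries are too few to be split, so part of any excess may come from the shared controls. The simulated values are means of 5 sets in which genes varied independently beyond the clusters, and no spread was kept. Exchanged labels gave correlations of up to 0.57 even between effects at 24 h and 48 h, which share no library. Departures from the simulated values in either direction are therefore not told apart from chance.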

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

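Both values below concern reads that the comparisons did not use, and they were picked out because they lie above all 9 DMSO libraries. In replicate 3 of TCPP at the high concentration at 48 h, 16.8% of the listed reads were placed at more than 1 position, where the DMSO libraries reached at most 11.8%. In replicate 2 of EHDPP at 48 h, 2.63% of reads were ambiguous between genes, against at most 2.56% in DMSO. The test for outlying libraries used within groups needs at least 4 libraries and was not run on groups of 3, and no test against the spread pooled over groups was run. The differences between the 24 h and 48 h effects called 0 genes for each compound.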

How the results depend on the processing

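The covariate for library clusters and the fit without the 2 libraries of highest share of reads outside genes were chosen after the data were seen; the other settings were planned. All 22 counts of called genes stayed within 1.5 times of their value with RLE size factors, without a filter and in fits of the compared groups only, and 18 did so with DESeq2. DESeq2 called 34 genes in DMSO between 24 h and 48 h, 1 for EHDPP at 48 h, 3 for the mixture at 48 h and 1 for the mixture over both times, each against 0. With surrogate variables, DMSO at 24 h against 0 h gave 7304 genes, including all 4588 in the same direction, and DMSO between 24 h and 48 h gave 433. The mixture gave 2 genes at 24 h, 2 at 48 h and 4 over both times with them. With the cluster covariate, DMSO between 24 h and 48 h gave 6 genes and high minus low TCPP gave 1. Without the 2 libraries, replicate 3 of DMSO at 48 h and replicate 3 of TCPP at 48 h, DMSO between 24 h and 48 h gave 2 genes and the mixture at 48 h gave 1. The surrogate variables lowered the common dispersion from 0.154 to 0.053 and the cluster covariate lowered it to 0.078. This does not account for all gained calls, since 2 of the genes called for the mixture over both times with surrogate variables also changed in fold, from 0.48 to 3.26 and from 1.11 to 3.11 on the log2 scale. The other 2 did not, at −3.93 and −3.87 and at −0.75 in both fits. For each of these alternatives the cause was not tested.

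With each library left out in turn, DMSO at 24 h against 0 h gave 3252 to 4376 genes, lowest without replicate 3 of DMSO at 24 h. DMSO at 48 h against 0 h gave 4913 to 5873, lowest without replicate 2 of DMSO at 48 h. The other 20 comparisons gave 0 by edgeR in every such refit. Their numbers of genes at an unadjusted p under 0.05 were less stable: in 19 of the 22 comparisons, leaving out some library moved the number by more than 1.5 times. The exceptions were DMSO at 24 h and at 48 h against 0 h and the mixture at 48 h. A group left with 2 libraries took its spread from all groups. The 4 printed identifiers kept their direction and an adjusted p under 0.05 in all 100 tests of an identifier at 24 h or 48 h under another setting. Their log2 fold changes at 24 h ranged from 9.09 to 10.32 for ENSGMOG00000005503, 7.20 to 9.62 for ENSGMOG00000016719, −6.21 to −4.43 for ENSGMOG00000011063 and −5.13 to −4.16 for ENSGMOG00000017338.

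No paired analysis was possible because the labels give no replicate or donor number; the cluster covariate above is a block taken from the data, not from the labels. The planned tests of gene lists, with their alternatives for the correlation between genes, were not run, since the identifiers matched no symbols. The planned split of the DMSO libraries between compounds was not possible with 3 libraries at a time. The libraries held 10847723 to 18271278 counts, and 6842 of the 22154 genes had too few counts to be tested. At an equal 10847723 counts, TCPP, EHDPP and the mixture over both times had 169, 197 and 751 genes at an unadjusted p under 0.05, beside 186, 204 and 784 at full depth.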

Other observations

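The simulated sets with independent genes were run, and clusters were used as strata, after the clusters were seen. The overlap with the DMSO calls, the exchanges of DMSO libraries within clusters, the measures by cluster, the placing of the 0 h libraries and the correlations between times had no bound written before their results. The other tests had one, for patterns found in the same data.

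Genes were also called between 24 h and 48 h in the exposed explants. Over the 18 libraries of TCPP, EHDPP and the mixture at the high concentration, 388 genes differed between 48 h and 24 h by edgeR, 156 higher and 232 lower (adjusted p under 0.05). With the cluster covariate 1571 genes were called, and with surrogate variables 2612. The number called was not set beside regroupings of these 18 libraries. These libraries share none with the DMSO comparison of 24 h with 0 h. Of the 156 genes that rose, 77 had also risen by 24 h in DMSO and 7 had fallen, where independent lists would give 26.8 and 19.9. Of the 232 that fell, 88 had fallen by 24 h in DMSO and 17 had risen, where independent lists would give 29.7 and 39.8. A further 72 of the rising and 127 of the falling genes were not called in DMSO at 24 h.

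In the DMSO libraries by themselves edgeR called 0 genes between these times, while DESeq2 called 34, the fit with surrogate variables 433 and the fit with the cluster covariate 6. In each of TCPP, EHDPP and the mixture by itself, with 3 libraries against 3, edgeR also called 0 genes, with 1226, 770 and 807 at an unadjusted p under 0.05 beside 1480 in DMSO. A change confined to the compounds is argued against by the DMSO libraries, for the 388 genes as a set. The 388 genes moved in the compound direction by 0.92 on average there, in log2 CPM, and this was the largest of the 20 signed splits of the 6 DMSO libraries (exact permutation test, one-sided p = 0.05, the smallest it allows). These splits take the 6 libraries as exchangeable. Exchanges of times within clusters allow 8 arrangements, of which the real one was the largest (exact permutation test, one-sided p = 0.125, the smallest it allows). With so few arrangements this second test cannot decide. The change was 1.3, 0.81 and 0.65 in the 3 clusters (SD 0.34). In fitted log2 fold changes the mean was 1.02 in DMSO and 1.06 in the compound libraries, and 380 of the 388 genes had the same sign. Single genes were not tested in this way, so a change specific to the compounds in some of them stays open. A continuing change with culture time, whatever the exposure, is a candidate explanation found and tested on these data.

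The 3 clusters, a number that was set and not estimated, hold 1 library of each of the 10 groups. Part of this balance comes from removing the group means, which sets the libraries of a group apart. In draws of independent libraries with the covariance between genes seen in the data, clustered in the same way, a median of 5 groups had 1 library in each cluster. All 10 groups did in 2 of 1000 draws, which argues against independent libraries. With independent genes as well, 0 of 100 simulated sets reached all 10 and the highest reached 9. The 56.1% of spread on 2 components is no evidence on this, since the draws had a median of 61.5%. Depth is argued against by counts thinned to an equal 10847723, where 30 of 30 libraries kept their cluster. The shares of reads outside genes and of multiply placed reads are argued against as well, since 29 of 30 libraries kept their cluster once each gene's trend with both shares was removed. For the number of genes detected, 40.5% of the variance within groups lay between the clusters, with means of 16930, 17390 and 17300 over 10 libraries each. At a permutation p of 0.011, or 0.055 adjusted over 5 measures, a difference stays open. Whether the structure precedes culture stays open too. The deviations of the 0 h libraries correlated at 0.50 to 0.55 with those of the cultured libraries of their cluster. Of the 1000 draws, 495 put the 0 h libraries in 3 different clusters, as in the data, and 142 of these 495 had as high a lowest value. Tissue of 3 fish divided over all treatments is a hypothesis that would give this pattern, as would library batches, and neither was tested because the labels name no fish or batch. If it holds, the comparisons are blocked by design, and a fit of group means alone overstates the error. In simulated data with these clusters and no change outside 200 genes, 362 of the other genes had an unadjusted p under 0.05 for TCPP at 24 h, against 704 with independent libraries and 788 with clusters and their covariate. The real libraries gave 123 such genes without the covariate and 250 with it, below the simulated 362 and 788. The clusters as simulated therefore leave part of the low real count unaccounted for.

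The mixture against DMSO over both times had 784 genes at an unadjusted p under 0.05, beside 186 for TCPP and 204 for EHDPP. In 1 simulated set of libraries with the clusters and no change outside 200 genes, 336 of the other genes had such a p. With 1 library left out, TCPP reached at most 406, without replicate 3 of DMSO at 48 h, and EHDPP at most 402, without replicate 1 of EHDPP at 24 h. Deeper mixture libraries are argued against as the cause by the 751 genes counted at equal depth. A single library is argued against too, as leaving out 1 of 12 gave 543 to 1235 genes, lowest without replicate 3 of DMSO at 24 h and highest without replicate 2 of DMSO at 24 h. Chance stays open: when treatment and DMSO labels were exchanged within clusters, 8 of the 32 exchanges gave as many genes as the real labels, 1351 in the fit of the 12 compared libraries with the cluster covariate, and the highest other gave 3381. For TCPP and EHDPP 22 and 28 of 32 did. The same fit called 1 gene for the mixture, which 4 of the 32 exchanges reached, and the highest other called 136. An effect of the mixture is therefore a hypothesis that these libraries do not settle.

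Effects at 24 h and at 48 h share no library, so a common response should correlate between the times. The correlation across genes was 0.32 for the mixture with itself, 0.0014 for TCPP with itself and −0.12 for EHDPP with itself. The permutation p for exchanges of labels within clusters was 0.12 for the mixture and at least 0.5 for TCPP and EHDPP, one-sided. Over all 9 pairs of an effect at 24 h with an effect at 48 h, the lowest p adjusted by Benjamini-Hochberg was 0.63. Genes are not independent replicates, and the p-values rest on 32 exchanges of libraries.

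Other splits of the libraries were refitted on the compared libraries only. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For DMSO at 24 h and 48 h against 0 h the real labels called 3408 and 5072 genes, the highest other split called 0 in both cases, and 1 of the 10 splits, the real one, called as many. In the other 11 such comparisons the real labels called 0 genes, which all 10 splits reach, as any split must, and the highest other split called 7 for TCPP at 48 h, 2 for the mixture at 24 h, 657 for EHDPP against TCPP at 24 h and 0 in the remaining 8. For the 9 comparisons over both times the real labels called 0 genes, and all 100 splits drawn within times reach that, as any split must, so these numbers of calls do not bear on chance. Their highest other splits called 1529 for TCPP, 629 for EHDPP and 117 for the mixture. For mixture minus TCPP, mixture minus EHDPP and mixture minus the sum of both effects they called 1, 871 and 1. For the 48 h effect minus the 24 h effect they called 2467, 629 and 117 in the same order of compounds. The numbers of genes at an unadjusted p under 0.05 do bear on chance. For the effects over both times, the real labels gave 118 for TCPP, 96 for EHDPP and 676 for the mixture. As many came from 84, 94 and 42 of the 100 splits, the real one included, and the highest other splits gave 4889, 3528 and 3497. Some splits thus set these libraries further apart than the real labels do. Whether those splits follow the 3 clusters was not tested.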
